A study of Mus musculus with 419 samples.

How the data were processed

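The series holds 419 single G1 embryonic stem cells of the female hybrid line F1-21.6, which carries 1 set of chromosomes from strain 129 and 1 from CAST, grown on laminin without feeder cells, per the labels. Each cell was read by RamDA-seq, a full-length method for total RNA without molecular identifiers. The labels name no separate cultures, so the 419 cells were treated as 1 sample. No p-value, standard error or count of tested genes was made from cells, and genes are named by fixed rules of size. Cells were sequenced in 5 lanes, which hold 88, 83, 82, 80 and 86 cells. Spreads given over lanes are between sequencing lanes and may be technical.

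The authors deposited 2 tables, 1 for each allele, with 117762 Ensembl transcripts as rows and 1 column per cell. All columns matched a sample title, and 0 columns were left unmatched. Bowtie 1.1.2 and the mouse build mm10 are named in the submitters' processing notes without their role; the tool that assigned reads to alleles and scaled the values is not given in the sources used here. The deposited values are whole numbers, but they are not raw counts: their unit was taken as a score, that is, estimated allele counts scaled by the authors to a nearly common total and rounded. The design, fixed before the data were examined, had assumed counts. Tests and intervals for counts of reads were therefore not used, the depth in reads is unknown, and no binomial interval is given for an allele share. Exact binomial intervals are given for shares of cells only, and they cover counting error only.

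Totals per cell were 416357 ± 27510 (SD over 419 cells) in the 129 table and 509052 ± 35968 in the CAST table, and the sum of both ranged from 698363 to 1477656. Rows for 2 ribosomal RNA genes, Gm26917 and CT010467.1, took 15.3% ± 2.46 (SD over 419 cells) of a cell's total. Every row on chromosomes X, Y and M is 0 in the 129 table, while the CAST table holds values for them. Rows were joined to the GENCODE vM21 annotation, which is on mm10 coordinates; 116919 rows matched, and the others hold 0.360% of all values.

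A gene was represented by its row with most counts, as fixed before the data were examined. Genes entered when their pooled value was at least 1000 and at least 10% of cells had a value above 0. A rule for rows without allele information was added after the data were seen. In some rows the 2 tables hold the same value in every cell apart from a factor per cell (median 1.01), as if reads without strain variants had been split evenly. Rows whose squared difference between alleles, after that factor, summed to less than 0.5 of their total were left out, which removed 544 of 11012 autosomal genes and left 10468. Some rows that stayed, such as those of Pou5f1 and Adnp, hold nearly alike values in most cells, so their low intrinsic noise may reflect the same split. For chromosome 12, the limits of 70 and 80 Mb and of 35%, 42% and 58% were chosen after seeing the data, as were the limits of 20% and 80% for single chromosomes in single cells, first looked at with 10% and 90%.

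For the noise measures, cell totals over both alleles were scaled to their mean. Genes needed a mean of at least 5 per cell from each allele and a 129 share of 10% to 90%, which left 6027. Intrinsic noise is the mean over cells of the squared difference between the mean-scaled alleles, divided by 2. Shared noise is the mean product of the mean-scaled alleles minus 1. The residual of log2 intrinsic noise is its distance from the running median of genes ranked by mean. A gene list was called apart when the median residual of its members lay within the lowest or highest 2.5% of 10000 random lists of the same size matched on mean; lists with under 5 measured members give values only. The burst frequency proxy is 1/(allele intrinsic noise - 1/mean), and the size proxy is the mean over the frequency. Both include capture and amplification noise, and sizes are in the authors' scaled units, not molecules.

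The rule for named genes was fixed before the data were examined. It took the 10 genes with most counts at or above 80% 129 and the 10 at or below 20%, without predicted symbols and imprinted genes, and the 10 genes of the fixed imprinted lists with most counts. It also took the 10 highest and 10 lowest noise residuals and the 5 largest frequency and size ratios among genes with at least 20 per allele, and up to 4 members of each list, the 2 highest and 2 lowest. For X-linked genes the rule ranked by share, which was 0 in all of them, so those with most counts are named. Markers of cell states, Meg3, Slc2a3 and Esrrb as examples of the burst split, Rps26 and Rnf2 as examples of shared noise below 0, and the genes used as examples of single-allele cells were picked outside this rule after their values were seen. Some genes that these rules pick are not reported here. No doublet caller was run and no cell was left out.

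The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. They were tested on simulated data with the means and cell totals of 6027 genes. For the burst split, 100 genes with a 2-fold and 100 with a 4-fold change in burst frequency gave 94.3% and 101% of the change as frequency, and the same numbers of genes with changed burst size gave -5.13% and -1.25%. The simulated burst frequencies were set independently of the mean, with Poisson sampling only. This test therefore does not cover technical noise beyond 1/mean. For the list comparison, a list of 20 genes with 2-fold more intrinsic noise had a median residual of 0.97 and lay at percentile 100, and 4.50% of 200 unchanged lists were called apart. For the size rule, all 100 of 100 genes with a true share of 85% were found at or above 80%. With binomial draws from pooled values of at least 1000 this outcome was nearly certain. It does not test the assignment of reads to alleles, sequence copies or the choice of row. Sequence sharing was measured as the percentage of a row's 31-base stretches that occur in transcripts of another gene of vM21, using a fixed 1 in 8 of all stretches.

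Alternatives covered the weight of cells and genes, count minimums, share thresholds, centring, all rows of a gene summed, lanes left out, cell scaling, extreme values, detection limits and thinning. Others were chosen after seeing the data: autosomes only, evenly split rows kept or removed more strictly, chromosome 12 left out, genes with shared sequence left out, 2 unusual cells left out, and matching on transcript length. The RNA spike-ins named in the extract protocol were not used here.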

Results

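The series set out to measure the kinetics of transcriptional bursting across the genome by reading both alleles of each gene in single cells. It holds 1 group of 419 G1 embryonic stem cells of a 129/CAST hybrid line, and its comparison is between the 129 and CAST alleles within each cell. Every cell had both alleles scaled by the authors to similar totals, with a median of 925852 per cell over both alleles and 29245 ± 1474 (SD over 419 cells) transcripts above 0. No replicate cultures are named, so the values describe these cells only. The chromosome 12 limits in position and share were chosen after the data were seen.

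The first comparison asked how expression divides between the alleles. Most autosomal genes were read about equally from both: the median 129 share of 10468 genes was 50.0%, the middle of the distribution ran from 45.3% to 54.6% (quartiles), and 76.6% of genes lay between 40% and 60%. At the extremes, 153 genes were at or above 80% 129 and 182 were at or below 20%. In every one of the 5 lanes alone, 74.5% of the former and 75.3% of the latter were beyond the same limits. Protein-coding genes made up 93 and 104 of the 2 groups, and pseudogenes 25.5% and 25.8%, against 1.82% of all measured genes.

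Ubb, a ubiquitin gene (chromosome 11, 62551171 to 62553213, mm10), was at 99.0% ± 0.422 129 (SD over 5 lanes). Summed over all annotated rows of the gene, it was at 67.4%. Lars2, the mitochondrial leucyl-tRNA synthetase, held 9879653 in the 129 table and 9438 in the CAST table (99.9% 129). Its 129 sum lies close to the CAST sum of the mitochondrial mt-Rnr2, 9248775, while the 129 table holds no mitochondrial values, so its share is uncertain as a measure of allelic expression. Among the other genes read mainly from 129, Nfatc3, a calcium-regulated transcription factor, was at 99.7%, Rpl37rt, a copy of a ribosomal protein gene, at 99.4%, and Cdk4, a kinase of the G1 phase, at 90.2%. Mir6236 was at 92.0%, but an alternative for the pooled share left it out together with the ribosomal RNA rows, so its share is uncertain. Cmah, an enzyme of sialic acid synthesis, was at 88.7%, Tomm22, part of the mitochondrial import complex, at 88.2%, Rps15 at 85.9% and the chaperone Dnajb6 at 84.5%. With all rows summed, Rpl37rt, Dnajb6, Tomm22 and Cdk4 lay at 79.2%, 71.5%, 74.6% and 70.3%.

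Towards CAST, Glo1, which detoxifies methylglyoxal, was at 9.38% 129, Rpl27a at 11.2%, the zinc finger gene Zfp987 at 11.5% and Ywhaz, a 14-3-3 protein, at 13.3%. The chaperone Hsph1 was at 17.6%, the centromere factor Hjurp at 17.8%, Tenm4 at 17.8%, Ttc7b at 18.4% and the coatomer gene Arcn1 at 19.0%. With all rows summed, Hsph1 was at 37.1%, Rpl27a at 24.2%, Tenm4 at 23.7%, Hjurp at 22.8% and Arcn1 at 20.2%. Of these genes, Ubb, Rps15, Rpl37rt, Dnajb6, Rpl27a, Ywhaz, Glo1 and Zfp987 share more than 20% of their row's sequence with other genes, so their reads may have been divided among copies and their shares are uncertain. Without all such genes, 81 genes were at or above 80% and 74 at or below 20%.

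**Figure D1:**
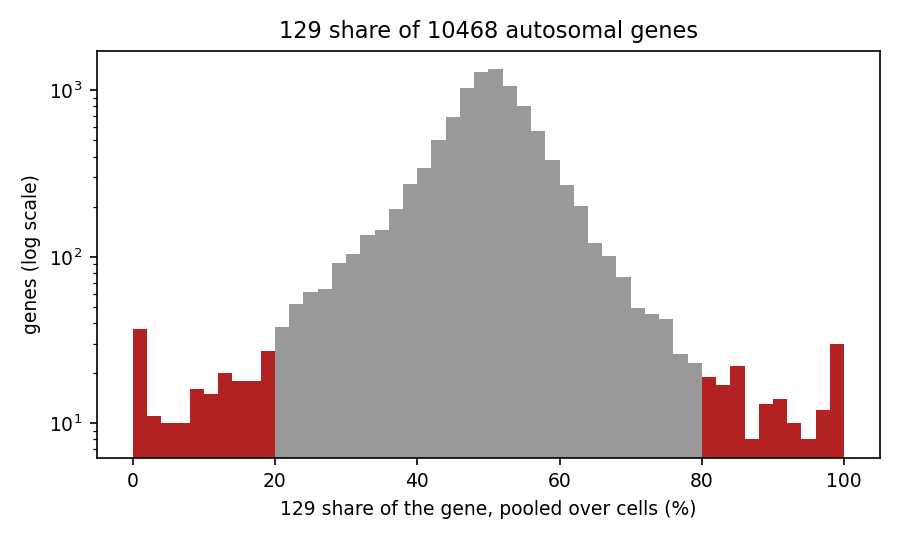
Number of autosomal genes (vertical axis, log scale) by 129 share of their values pooled over 419 cells (horizontal axis, percent). Red bars hold the 153 genes at or above 80% and the 182 at or below 20%; the median of 10468 genes is 50.0%.

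Over all genes and chromosomes the pooled 129 share was 44.6%, and it ranged over the lanes from 44.5% to 44.9%. The figure is lowered by chromosomes that have no 129 values at all; over autosomal genes only, an alternative chosen after seeing the data, it was 49.1%. The design also asked how X-linked reads divide in this female line. All 1758 X-linked genes with any value were 0 in the 129 table, as were all Y-linked and mitochondrial rows. The X-linked 129 share of 0% may therefore be set by how the tables were made, which was not tested. No statement about the X chromosomes is drawn from it. The CAST table held X-linked genes at high levels, such as Usp9x at a mean of 1084 per cell, Huwe1 at 1000 per cell and Rps4x at 786. Xist, the RNA that coats an inactive X chromosome, had a CAST sum of 81199.

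Of the 27 measured genes of the imprinted lists, which in tissues are transcribed from 1 parental allele, 23 had a pooled 129 share between 20% and 80%. Kcnq1ot1 was at 50.2% ± 1.99 129 (SD over 5 lanes), H19 at 50.4% ± 5.66 (with 42.0% of its sum in 4 cells and only 1 allele in 56.6% of the cells with a value), Impact at 52.3% ± 1.27, Zdbf2 at 46.5% ± 2.56, Snrpn at 45.7% ± 1.73, Peg10 at 40.4% ± 2.02 and Peg3 at 37.0% ± 2.79. The noncoding RNAs Meg3 and Rian and the gene Rtl1, neighbours on chromosome 12 (Meg3 at 109545398 to 109571726, mm10), were at 18.5%, 18.1% and 18.1%. That part of chromosome 12 was shifted towards CAST as a whole: genes beyond 80 Mb had a median 129 share of 30.2%, and of the 182 genes at or below 20% in the genome 14 lie there.

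Chromosome 12 was the only autosome whose genes departed from equality. Its 416 genes had a median 129 share of 38.1%, while the medians of the 18 other autosomes lay between 49.5% and 51.4%. The shift began between 70 and 80 Mb. Windows of 10 Mb below 70 Mb had median gene shares from 50.0% to 52.4%, and those from 80 Mb on from 28.6% to 31.5%. The cells did not share it evenly: beyond 80 Mb, 290 of the 419 cells were under 35% 129, 114 were between 42% and 58%, 7 lay between 35% and 42%, and 8 were at 58% or more. Below 70 Mb, 408 of 419 cells were between 42% and 58%. In each lane, 64.6% to 73.8% of cells were under 35% beyond 80 Mb.

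**Figure D2:**
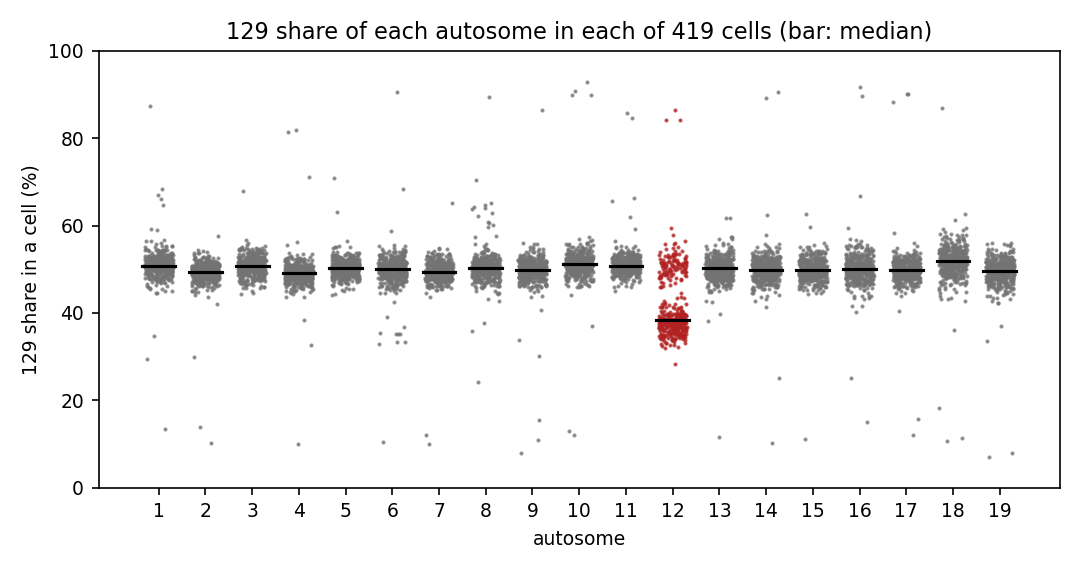
129 share of each autosome (horizontal axis) in each cell (points; vertical axis, percent), with each gene weighted equally and genes beyond 20% or 80% left out; bars are medians over 419 cells. Chromosome 12 (red) has a median of 38.5% and most of its cells in a separate band; single cells lie near 10% or 90% on other autosomes.

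**Figure D3:**
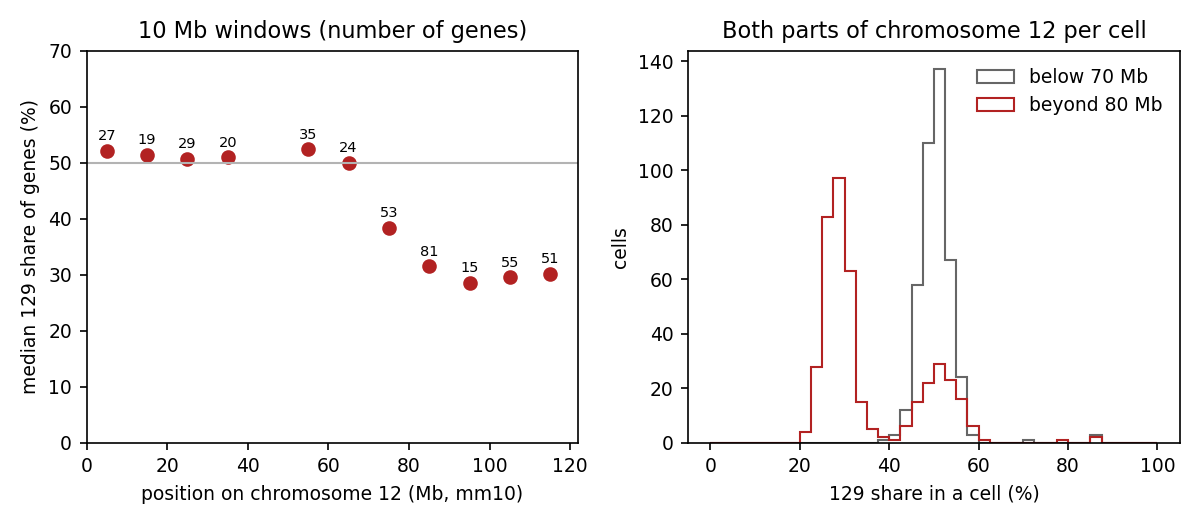
Left, median 129 share of genes (percent) in windows of 10 Mb along chromosome 12 (mm10) with the number of genes in each. Right, number of cells by 129 share below 70 Mb (grey) and beyond 80 Mb (red); 290 of 419 cells lie under 35% beyond 80 Mb.

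The next comparison asked how often both alleles of a gene are seen in 1 cell. Among 6027 genes with a mean of at least 5 from each allele, a median of 23.5% of the cells with any value had only 1 allele (quartiles 7.16% and 40.8%). Alleles seen independently of each other would give 24.5%. Among genes picked as examples, the pluripotency gene Dppa4 had only 1 allele in 1.94% of cells and Dnmt3l in 4.38%. The growth factor target Dusp6 had only 1 allele in 38.4% and the keratin gene Krt8 in 49.0%. Their levels differ: the median cell held 49 for Dppa4, 296 for Dnmt3l and 5 for Krt8. No share expected from independent alleles is set beside these examples, so they do not separate allele behaviour from level. The median over genes depends on the rows used: it was 5.49% for genes with a mean of at least 20 per allele. With all rows of a gene summed it was 9.31%.

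Variation between cells was then divided into intrinsic noise, in which the alleles of a cell differ, and shared noise, in which they move together. Intrinsic noise made up nearly all of what remained after scaling: its median was 0.706 and that of shared noise -0.026, so the median intrinsic share was 106%. The authors had scaled cells to nearly common totals, and totals were scaled again here before the split. Variation common to all genes of a cell was thus largely removed, so the low shared noise can partly follow from the scaling. Intrinsic noise here includes noise of capture and of assigning reads to alleles: Rps26, with an intrinsic noise of 0.831, had a shared noise of -0.37, and Rnf2, with 1.37, had -0.43. Shared noise was below 0 in 57.1% of genes, which was not compared with the share that independent alleles would give. Intrinsic noise fell from a median of 1.28 at 5 to 10 per allele to 0.115 at 100 or more, while shared noise went from -0.101 to 0.028.

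Among the genes with most intrinsic noise for their mean, Sfmbt2, a Polycomb-related gene, had an intrinsic noise of 2.46 and a residual of 4.49 (log2), with little shared noise at 0.102. The endocytic receptor Lrp2, the matrix gene Thbs1 and the smooth muscle actin Acta2 followed with residuals of 3.81, 3.54 and 3.40, and the cytoskeletal genes Tagln and Vim had 2.91 and 2.60. The noncoding RNAs H19, Neat1, Meg3 and Rian had 3.24, 3.23, 3.10 and 2.60. The 4 highest cells held 75.4% of the sum of Acta2, 49.5% of Thbs1, 42.0% of H19, 29.9% of Tagln and 20.6% of Lrp2. They held 16.1% of Vim and 7.60% of Neat1. Residuals of genes concentrated in few cells can rest on those cells. At the other end stood Snhg14 (also noncoding), Tmem72, Adnp, Fubp3, C1qbp and Ppp1r2, with residuals from -8.34 to -3.41, and Ahcyl1 with -2.50. The alleles of Tmem72, Adnp, C1qbp, Ppp1r2, Fubp3 and Ahcyl1 differed by no more than 10% of their sum in 94.2% to 100% of cells, as in rows without allele information. The ribosomal protein genes Rpl36, Rps29 and Rps3a1 had residuals of -2.70, -2.69 and -2.53.

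Gene lists fixed before the data were examined differed in intrinsic noise at matched mean, and 7 of the 19 lists with at least 5 measured members stood apart. Ribosomal protein genes were the quietest: the median residual of 62 members was -0.94, lower than in all 10000 random lists (percentile 0), with Rpl36 and Rps29 lowest and Rpl32 (1.82) and Rps23 (1.67) highest. The call held in the 16 alternatives that gave this list a value, where most lists had 17. No percentile without genes sharing sequence is reported here for it, and lists with under 5 measured members were given none. The 16 alternatives therefore do not test shared reads. Ribosomal protein genes such as Rps15 and Rpl27a share such sequence, so a part played by shared reads stays open. The 18 replication genes of the S-phase list were also low, with a median of -0.67 (percentile 0.190), from Rpa2 at -1.64 and Ung at -1.05 to Slbp at 0.54. Maternally expressed imprinted genes were the noisiest, with a median of 1.61 over 8 members (percentile 100), led by H19 and Meg3. Nuclear noncoding RNAs followed with 0.94 over 11 members (percentile 99.97; 97.4 with all rows summed), led by Neat1, and Snhg3 was the lowest of them. Paternally expressed imprinted genes had 0.75 over 11 members (percentile 99.8; 95.2 with extreme values limited and 96.6 without genes sharing sequence), led by Rtl1 (2.25) and Peg3 (2.11).

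Targets of ERK signalling were also above matched genes, with a median residual of 0.57 over 15 members (percentile 99.7); among genes with at least 20 per allele, 6 members had 0.67 (percentile 96.7). The phosphatase genes Dusp5 (1.89) and Dusp6 (1.44), feedback inhibitors of the pathway, were highest, and Spred1 (-0.35) lowest. Genes of the AKT and mTOR pathway had 0.45 over 18 members (percentile 98.9), led by Gsk3b (1.43), but fell back to percentile 71.2 among genes with at least 20 per allele. The call was also lost with all rows summed (percentile 93.3) and matched on transcript length (95.4). Naive and core pluripotency genes did not stand apart, at percentiles 87.7 and 85.9, although with all rows summed the naive list was at 97.7. Among them Esrrb (1.93) and Dnmt3l (1.25) were noisy and Pou5f1 (-2.44) and Dppa4 (-1.43) quiet, and in Pou5f1 the alleles lay within 10% of their sum in 96.2% of cells. Polycomb and Trithorax genes were at percentile 92.4, elongation and pausing factors at 77.5, heat shock genes at 78.8, glycolysis at 67.2, housekeeping genes at 24.2, p53 targets at 29.2, G1/S genes at 39.2, G2/M genes at 5.06, formative genes at 87.6 and primitive endoderm genes at 97.2. Meg3, Rian, Rtl1 and Esrrb lie in the part of chromosome 12 where the cells differ in CAST share, and the genes measured there had a median residual of 0.32.

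**Figure D4:**
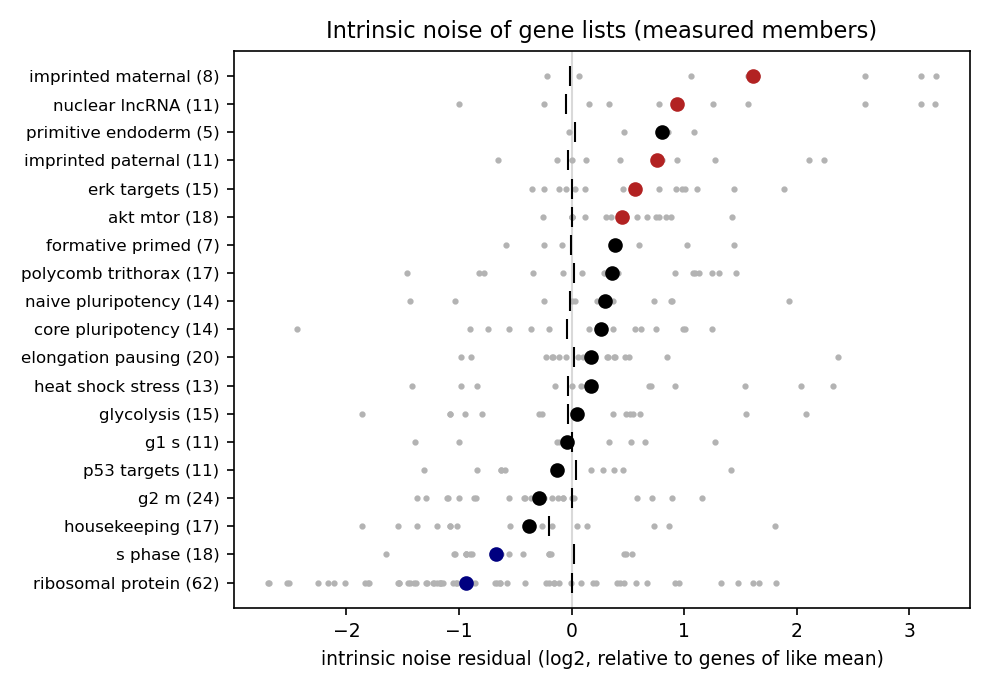
Residual of log2 intrinsic noise from genes of like mean (horizontal axis) for the measured members of 19 gene lists (grey points, number in brackets), with the list median (large point) and the median of 10000 matched random lists (tick). Red and blue medians are the 5 lists above and the 2 below the random range; ribosomal protein genes are lowest at -0.94.

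The last comparison of alleles asked whether unequal expression comes with a different burst frequency or a different burst size. Of 331 genes with at least 2-fold different allele means and both proxies, the frequency proxy carried a median of 85.5% of the log2 mean ratio (quartiles 56.4% and 106%), and it carried at least 50% in 261 genes. The proxy subtracts only 1/mean, while median intrinsic noise over genes fell from 1.28 at 5 to 10 per allele to 0.115 at 100 or more. Technical noise that falls with the mean and stays in the proxy would make it follow the mean. The split therefore cannot show that the alleles differ in burst frequency. CAST was the higher allele in 224 of the 331 genes and 129 in 107, and 92 lie on chromosome 12 beyond 80 Mb. Many cells may carry an additional CAST copy of that part, so the proxies of genes there can reflect copy number. Without chromosome 12, the frequency proxy carried a median of 95.1% in 218 genes. Meg3, an imprinted gene in that part, had a log2 129/CAST mean ratio of -2.13, a frequency ratio of -2.19 and a size ratio of 0.05. The glucose transporter gene Slc2a3 had a log2 mean ratio of 1.61 with a frequency ratio of 2.64 and a size ratio of -1.04. Esrrb, also on chromosome 12 beyond 80 Mb, divided its mean ratio of -1.83 into -0.96 for frequency and -0.87 for size.

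The largest frequency ratios among genes with at least 20 per allele were in genes whose means differed less than 2-fold. The log2 size ratio is the log2 mean ratio minus the log2 frequency ratio. Frequency and size therefore offset each other by definition where the means are alike. The basement membrane gene Nid1 had a log2 frequency ratio of 7.49 against a size ratio of -6.56, the myosin gene Myh9 6.81 against -6.71, the integrin genes Itgb1 6.31 against -6.07 and Itga5 5.45 against -5.28. The pluripotency factor Tfcp2l1 had a frequency ratio of 5.97 and a size ratio of -5.23, and Mreg 5.44 and -5.40. These ratios are poorly determined: for Mreg the log2 burst size ratio was 0.04 without sequencing lane 2.

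**Figure D5:**
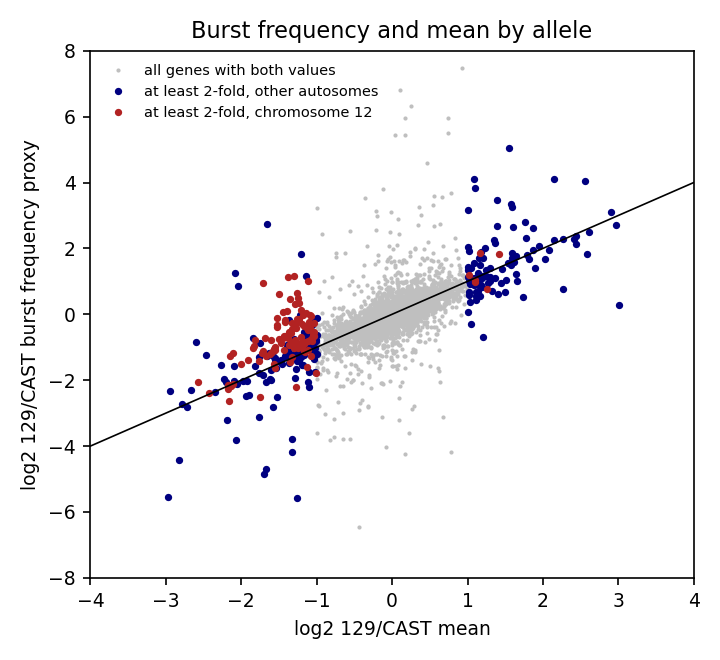
log2 129/CAST ratio of the burst frequency proxy (vertical axis) against that of the mean (horizontal axis) for 5944 genes, with genes at least 2-fold different in blue (chromosome 12 in red). On the line, the frequency proxy alone carries the difference in mean. The median share carried by the proxy was 85.5%, and 1 value lies outside the axes shown.

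Marker lists were used to count cells with members of lists for other states; a member above 0 does not by itself show that state. All 419 cells had at least 3 members of the naive, core and formative pluripotency lists, with Dppa5a at a mean of 920 per cell, Esrrb at 503 and Nanog at 156. Cells also had at least 3 members of the primitive endoderm list in 100% of cases, of the trophectoderm list in 97.6% (exact binomial 95% interval 95.7% to 98.9%), of the fibroblast list in 90.9% (87.8% to 93.5%), of the neural list in 58.2% (53.3% to 63.0%) and of the mesendoderm list in 34.6% (30.1% to 39.4%). Levels of the lineage regulators among them differed: Gata6 had a mean of 0.504 per cell, Sox17 0.048, Cdx2 0.687, Pax6 0.690 and Eomes 4.13, while Gata3 had 5.28, Sox7 8.42, Tfap2c 28.3 and Tead4 35.8. The laminin gene Lama1 had 219 and the fibronectin gene Fn1 504, while the mean of Krt8, 178, came with a median cell of 5 and a highest cell of 5998. With a value of 5 needed per member, the neural and mesendoderm figures were 26.0% and 4.30%.

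Members of the list for the 2-cell-embryo state were seen 3 or more at a time in 27 cells, 6.44% (4.29% to 9.24%), and in 8 cells (1.91%) at a value of 5 per member. One member, Eif1a, was above 0 in every cell, so 3 members stand for 2 others. Without Eif1a, 3 cells held more than 1000 in the list. The part of a gene's sum held by its highest cell ranged among the others from 16.5% for Usp17le, 45.3% for Zscan4a and 51.3% for Zscan4c to 92.8% for Zscan4d, 97.7% for Zfp352 and 99.9% for Tdpoz4. Replication and mitosis genes were present throughout the gate on G1, with at least 3 of each list in every cell; Mcm5 had a mean of 503, Pcna 205, Mki67 335 and Cdc20 316 per cell. The fibroblast collagen gene Col1a1 was above 0 in 25.5% of cells, with a median cell of 0, a highest cell of 2505 and a mean of 18.9, and the highest cell of Col3a1 held 82.8% of its sum.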

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

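The test of mitochondrial sequence in this part was chosen after the result was seen. Data outside the allele comparisons also held signal. The mitochondrial rows summed to 17870733 in the CAST table, led by mt-Rnr2 with 9248775, and to 0 in the 129 table. The Y-linked rows summed to 76839 in the CAST table of this female line, of which Gm37158 held 58993, and 83.0% of its sequence occurs in other genes. The Y-linked gene Kdm5d held 423, and its shared sequence was not measured.

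The 129 table had no mitochondrial values, but 6 pseudogenes on chromosome 1, Gm28661, Gm29216, Gm28437, Gm10925, Gm10222 and Gm28438, share at least 20% of their sequence with mitochondrial transcripts, and their median 129 share was 99.974%. This is what mitochondrial reads of the 129 table placed on nuclear copies would give, so that placement may explain these genes, as a hypothesis found and tested on the same data. Lars2 had a 129 sum of 9879653 but shares 0% of its sequence with mitochondrial transcripts, so this test does not extend to it. No biological explanation was tested.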

How the results depend on the processing

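Tests of autosomes only, chromosome 12, shared sequence, transcript length, evenly split rows and 2 unusual cells were chosen after seeing the data. The pooled 129 share was 47.6% with genes weighted equally, 45.0% with all rows summed, 49.1% over autosomal genes and 49.2% without ribosomal RNA rows, Lars2 and Mir6236. Genes at or above 80% and at or below 20% made up 2.16% (318 genes) and 2.28% of 14737 genes at a minimum of 200, and 1.25% (76) and 1.49% (91) at a minimum of 5000. They made up 0.707% (74) and 0.802% (84) at 90% and 10%, and 0.929% (81) and 0.849% (74) without genes sharing sequence, against 1.46% (153) and 1.74% (182). The single-allele share was 9.31% with rows summed, 5.49% at a mean of at least 20 per allele and 34.5% with a value of 5 needed. The intrinsic share was 99.5% at a mean of at least 20. The burst split was 80.1% at that mean, 88.1% without sequencing lane 2, 95.1% without chromosome 12 and 91.4% at 1.5-fold imbalance. With at least 2 members, cell state shares were 29.8% for the 2-cell list, 61.6% for mesendoderm, 99.5% for trophectoderm, 92.1% for neural and 99.3% for fibroblast; with a value of 5 they were 1.91%, 4.30%, 68.7%, 26.0% and 41.3%, and 98.3% for primitive endoderm. The log2 burst size ratio of Mreg reversed to 0.041 without sequencing lane 2. Of 54 alternatives each, 22 moved the burst size ratio and 19 the burst frequency ratio of a named gene by at least 1 log2 unit, a limit set without replicates.

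Alternatives ended 7 calls of single lists and made 8; the number of lists apart stayed within 1.5 times 7. The list noise of akt_mtor fell to percentile 93.3 with the sum over all rows of a gene, 71.2 at a mean of at least 20 and 95.4 matched on transcript length with the residual still 0.45, that of erk_targets to 96.7 at a mean of at least 20, where 6 members had a median residual of 0.67 against 0.57 over 15, that of nuclear_lncRNA to 97.4 with rows summed, and that of imprinted_paternal to 95.2 with extreme values limited and 96.6 without genes sharing sequence. The list noise of housekeeping genes fell to percentile 0.170 without genes sharing sequence and that of g2_m to 1.05 without lane 6. Calls were also made for naive_pluripotency (97.7, rows summed), heat_shock_stress (98.4 at a mean of at least 20, 97.8 with median-of-ratios factors), formative_primed (99.3 without lane 2) and primitive_endoderm (98.7 without lane 2, 98.0 matched on length). Fewer genes entered at a higher minimum (6097 at 5000, against 10468). The stricter share threshold of 90% and 10% kept all 10468 genes and moved only the limit. The cause was not tested for the other alternatives. Leaving out cells far under the median total was not run, since 0 cells met that rule. Thinning left out 11 cells. The depth in reads is unknown, so the limit it sets could not be computed. No paired analysis was possible because the cells form 1 sample.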

Other observations

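The test of mapping loss on chromosome 12 was chosen after the result was seen, and the limit of 80 Mb came from the windows. Loss of 129 reads in mapping would lower the share in every cell, but 28.9% of cells had a chromosome 12 share of at least 45%. A sequencing lane would concentrate the low cells, but in the lane with fewest, 64.6% of cells were under 42%. The shift lies in part of the chromosome, since a window of 10 Mb reached a median gene share of 52.4%. The range over cells of the log2 CAST level was 3.27 times that of the 129 level for chromosome 12. Beyond 80 Mb, the range of the log2 CAST level was 4.38 times that below 70 Mb. Many cells may thus carry an additional CAST copy of the distal part. The CAST level beyond 80 Mb ranged 3.29-fold over cells and the 129 level there 1.39-fold. Going from 1 CAST copy to 2 would by itself give a 2-fold range. Of the 290 cells under 35% there, 32 lay from 20% to 25%, 180 from 25% to 30% and 78 from 30% to 35%, while 1 copy of 3 would give 33.3%, so most lay lower than that; DNA was not examined.

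For genes read almost wholly from 1 allele, a candidate explanation is reads shared with similar genes: a median of 25.1% of their sequence occurs in other genes, against 0.725% in the other measured genes. The choice of 1 row per gene remained undecided, since 20% of them (67 of 335) lay between 20% and 80% with all rows summed. Strain differences in regulation were not tested and stay open for the rest.

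In 32 cells (7.64%), at least 1 autosome had a 129 share under 20% or over 80%. Of the 7961 pairs of cell and autosome, 23 were under 20% and 23 over 80%. Autosomes other than chromosome 12 also had 24 pairs between 28% and 40% and 31 between 60% and 72%. In 30 of these cells it was 1 autosome, in 1 cell 5 and in 1 cell 11.

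The cell with the highest total, 1477656, in lane 4, had 16 of the 17 measured members of the 2-cell-embryo list and 72.8% of all values of that list without Eif1a. Genes in this paragraph were picked after their values were seen. It held 3061 for Usp17lc, 1588 for Zfp352, 1513 for Zscan4d and 709 for Tdpoz4, and Tmem72 took 24.8% of its total. Its value was 12 for Esrrb, where the median cell had 510, and 24 for Pou5f1, whose mean over all cells was 177.0. Other abundant genes were also low in it: Eif1a was at 29 and Actb at 2307, and the cell had 21872 transcripts above 0, where the median cell had 29431.

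Shared noise was 134.6 in Tmem72, whose tables hold nearly the same values, so its alleles must move together. It was high in Acta2 (73.2), Thbs1 (26.9), H19 (23.3), Krt18 (22.4), Krt8 (16.3) and Tagln (11.8), which were picked after their values were seen. These values rest on few cells: the 4 highest cells held 75.3% of the sum of Tmem72, 75.4% of Acta2, 49.5% of Thbs1, 42.0% of H19, 36.3% of Krt18, 29.9% of Tagln and 27.4% of Krt8. The cell with the highest total alone held 66.9% of the sum of Tmem72. Slc25a20 (shared noise 68.5), outside the rule for named genes, had 50.1% of its sum in the same cell. Of 36 pairs among 9 such genes, the 10 highest cells overlapped most for Acta2 with Thbs1 and Krt8 with Krt18, by 8 cells, where 0.239 would be in common if unrelated. H19 shared 0 cells with Acta2 and 1 with Thbs1 but 3 with Krt8 and 3 with Krt18, and Vim shared 0 with Krt8 but 2 each with Acta2, Tagln and Thbs1.

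No alternatives were run for shared noise by list, and few cells can carry it. It was above matched random lists in 10 lists: naive pluripotency (median residual 0.33), core pluripotency (0.087), formative (0.45), primitive endoderm (0.69), glycolysis (0.12), ERK targets (0.69), p53 targets (0.74), nuclear noncoding RNAs (0.35) and maternally (0.41) and paternally (0.16) expressed imprinted genes. Ribosomal protein genes lay below, at percentile 1.09.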
